A study of Mus musculus with 16 samples.

How the data were processed

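RNA was measured in 16 libraries from mouse primary forebrain neuronal cultures transduced with lentiviral vectors, in 4 groups of 4. The groups are an empty vector, a hairpin, and the same hairpin with 2 or with 5 point mutations. Per the labels' protocols, total RNA was extracted with TRIzol and RNeasy columns, 100 ng was depleted of ribosomal RNA, and directional libraries were made with dUTP, 10 minutes of fragmentation and 12 PCR cycles. Per the submitters' processing notes, the authors used bcl2fastq 2.20.0.422, Trim Galore 0.6.0, cutadapt 1.15, STAR 2.7.2b against GRCm38.p6, featureCounts and edgeR, the last 2 without a version. The deposited file holds the raw counts that the authors made with featureCounts, as whole numbers for 55335 Ensembl genes in the 16 libraries. The strand setting, the treatment of reads with several matches and the annotation release were not stated. It is therefore not known whether the counting told apart reads of overlapping genes on opposite strands. This touches Rtn4, Nefm, Cp, Tcfl5, Dnah1, Tug1, Sirt2 and Ctsb among the genes named. The counts of the 37 genes of the mitochondrial chromosome were 0 in all libraries, so mitochondrially encoded genes are not measured here.

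Gene symbols, types, positions and 3′ UTR sequences came from GENCODE vM21 on GRCm38. Of the 55335 gene IDs, 54587 matched with their version and 55154 without it, and 181 did not match. Total counts ran from 33795369 to 49824569 per library, and 39067 genes had at least 1 count. Every library was used. Within groups, replicate libraries differed by more than counting noise (chi-square per degree of freedom 4.02 to 30.38), so no library was a copy of another.

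Genes were kept with filterByExpr on the groups (19479 genes), scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with robust dispersion, with 1 coefficient for each group and all 16 libraries in a single model. Pairwise contrasts of the 4 groups and the mean of the 3 hairpins against the empty vector were tested 2-sided. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called changed. CPM are counts-per-million with TMM scaling. The labels number the libraries 1 to 4 within each group and do not say that a number marks a shared culture, so the libraries were not treated as pairs. The comparisons, the tests, the lists of genes, the microRNA families and the rule for naming genes were fixed before the data were examined.

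Genes are named by 4 rules. The first takes the 10 highest and 10 lowest log2 fold changes of a contrast among changed genes with a mean log2 CPM of at least 2, no overlap between the libraries of the groups compared, and a symbol other than a predicted or clone name. The second takes the 10 genes with the largest smallest rise and the 10 with the largest smallest fall among genes changed in the same direction by all 3 hairpins, with the same filters. The third takes up to 4 members with the smallest p of each gene list in a contrast. The fourth takes all measured members of the lists of RNAi machinery and interferon sensors. Some genes that meet these rules are not reported here. Gm26917 and Gm42418 were chosen after their values were seen, because their shares of the counts differed between the groups.

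Of 33 gene lists written, 32 had measured genes. They cover neuronal and other cell types, synaptic, ion channel and axon guidance genes, RNAi machinery, microRNA host transcripts, genes repressed by miR-124, interferon and inflammatory genes, stress responses, p53 targets, immediate early and activity-regulated genes, cholesterol synthesis, lysosome, oxidative phosphorylation, ribosomal protein, histone, chromatin, cytoskeleton and injury genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast. Members past the threshold were counted over all genes and again with p adjusted over the list alone. The self-contained fry test and camera with a correlation estimated from the data were alternatives.

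For each of 27 microRNA families, a score per library was the coefficient of having at least 1 seed match (7 bases, or 8 with the flanking A) in the longest annotated 3′ UTR, in a regression across 14246 genes with a UTR of at least 50 nucleotides. The regression was of log2 CPM, centred on the mean of all libraries, and included log2 UTR length and GC content. Scores were compared between groups by exact permutation of the libraries (70 splits of 4 against 4, or 1820 of 12 against 4) and adjusted over the families. The slope of log2 CPM on log2 gene length was compared in the same way. All possible 7-mers found in the UTRs of at least 100 genes (15900) were scanned with the same regression on the fold changes. Scores and tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

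The pipeline was tested on simulated data with the depth and spread of the libraries, with 50 genes planted at each of 4 fold changes. The edgeR test recovered 26% at 1.2-fold, 64% at 1.5-fold, 68% at 2-fold and 92% at 4-fold, made 10 calls of genes that were not planted, and called 0 genes in an unchanged group. A list with a planted shift of 0.3 was called with an adjusted p of 5.03e-92 (1.86e-09 with an estimated correlation), and 1 of the other lists was called with it. A planted shift of 0.1 in the targets of a microRNA was recovered as 0.103, with at most 0.007 in the other families. The 4 empty-vector libraries split into 2 and 2 gave 0 changed genes in each of the 3 splits by edgeR.

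Alternatives for the gene counts were DESeq2's size factors and upper quartile factors for scaling, no filter or at least 1 CPM in 4 libraries, DESeq2 1.42.0 and limma voom as tests, a fit of only the groups compared, a fold threshold of 1.2, a block for the replicate number, and leaving out each library. For the microRNA scores they were 8-base sites only, genes with a mean log2 CPM of at least 4, no UTR covariates, the block and leaving out each library, and for the length slope the expression level, the block and leaving out each library. Chosen after the data were seen were protein-coding genes only, leaving out Gm26917 and Gm42418, leaving out genes with the 7-mers most lowered by a hairpin, and leaving out each library for the length slope.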

Results

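Total RNA was sequenced after ribosomal RNA depletion from mouse primary forebrain neuronal cultures of perinatal origin that had been transduced with lentiviral vectors. The 16 libraries formed 4 groups of 4. One group received an empty vector, and the others received a vector that expressed a short hairpin RNA (the unmutated hairpin), the same hairpin with 2 point mutations (the 2-mutation hairpin), or the same hairpin with 5 point mutations (the 5-mutation hairpin). A short hairpin RNA is processed by the cell's own microRNA machinery into a small guide RNA that lowers transcripts it pairs with, and mutated versions are commonly used as controls for that pairing. The labels did not name the transcript the hairpin was designed against. Total counts per library ran from 33795369 to 46187568 with the empty vector and from 36143806 to 41152791 with the unmutated hairpin. They ran from 41618901 to 49824569 with the 2-mutation hairpin and from 35521472 to 47401867 with the 5-mutation hairpin. Of 55335 genes in the table, 39067 had at least 1 count and 19479 passed the expression filter. The labels do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

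The transcript that fell furthest with the unmutated hairpin was Rtn4, which encodes the reticulon family protein Nogo, known as an inhibitor of axon growth. Rtn4 (ENSMUSG00000020458.16; GRCm38 chromosome 11, 29692947 to 29744331, plus strand) was measured at 863 ± 27.2 CPM (counts-per-million; SD, n = 4) with the empty vector and 30.5 ± 0.692 CPM with the unmutated hairpin, a 28.3-fold difference. It was intermediate, 127 ± 3.4 CPM, with the 2-mutation hairpin and 828 ± 37.2 CPM with the 5-mutation hairpin. The log2 fold change against empty vector was −4.82 ± 0.05 (SE; edgeR adjusted p = 8.86e-26) for the unmutated hairpin, −2.77 ± 0.04 (adjusted p = 3.39e-22) for the 2-mutation hairpin and −0.06 ± 0.04 (adjusted p = 0.203) for the 5-mutation hairpin. Each of the 4 libraries of a group lay within 29.9 to 31.3 CPM for the unmutated hairpin, 122 to 130 CPM for the 2-mutation hairpin, 773 to 856 CPM for the 5-mutation hairpin and 837 to 891 CPM for the empty vector. The gene Eml6 overlaps Rtn4 on the opposite strand, and the strand setting of the counting was not stated.

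**Figure D1:**
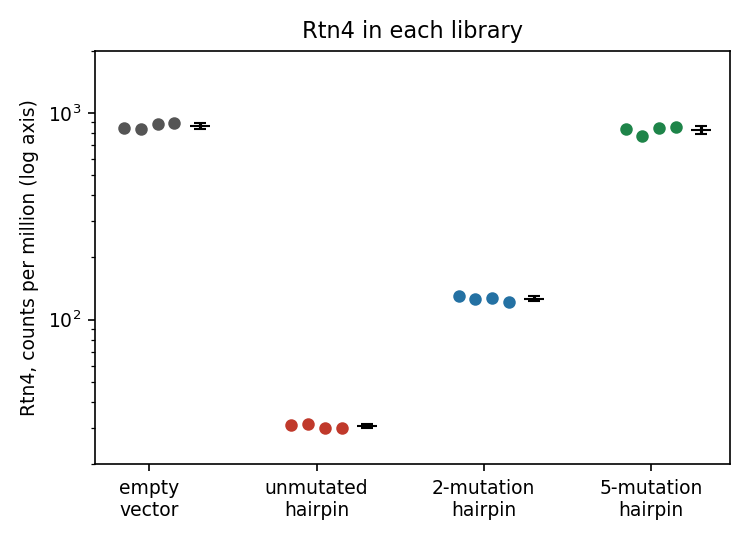
Rtn4 in each of the 16 libraries, in CPM on a log axis, by group, with the group mean and SD beside the points. The 4 unmutated-hairpin libraries sit between 29.9 and 31.3 CPM and the 4 empty-vector libraries between 837 and 891 CPM.

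Every hairpin vector changed a large share of the transcriptome relative to the empty vector. By edgeR's quasi-likelihood test at an adjusted p below 0.05, 7859 genes (40.3% of those tested) differed with the unmutated hairpin, 4054 higher and 3805 lower. The 2-mutation hairpin changed 12324 genes (63.3%), 6332 higher and 5992 lower, and the 5-mutation hairpin changed 10697 genes (54.9%), 5540 higher and 5157 lower. Most changes were modest: the median absolute log2 fold change of the changed genes was 0.38, 0.60 and 0.52, and changes over 2-fold were seen in 573 higher and 432 lower, 1069 higher and 2105 lower, and 1208 higher and 1194 lower genes, in the same order. In a principal component analysis the first component (40.8% of variance) set the 2-mutation libraries apart and the second (24.5%) the 5-mutation libraries. Principal component 3 (11.5%) set the empty-vector libraries, at 23.4 to 34.7, apart from the unmutated-hairpin libraries, at −37.4 to −31. The long noncoding locus Gm26917, known to collect reads of ribosomal RNA, took 6.16 ± 0.22% of counts with the empty vector, 7.61 ± 0.31% with the unmutated, 11.15 ± 0.24% with the 2-mutation and 8.75 ± 0.54% with the 5-mutation hairpin (SD, n = 4 each).

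**Figure D2:**
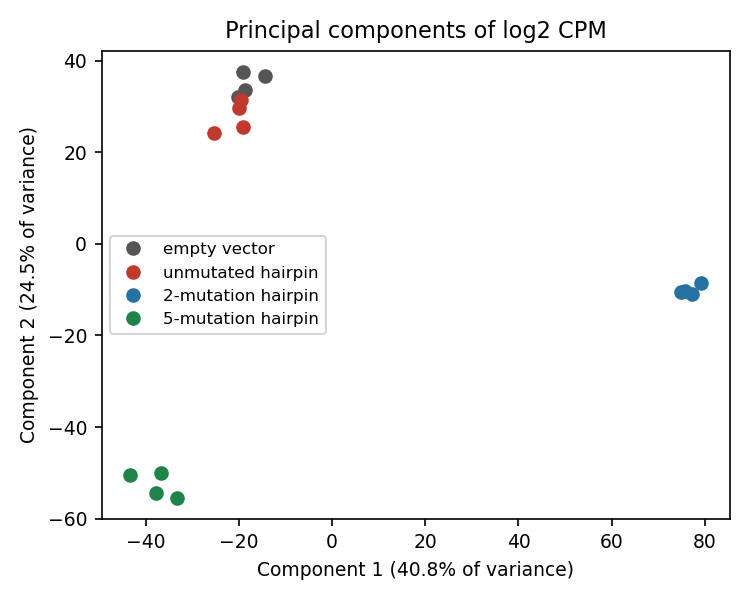
The 16 libraries on the first and second principal components of log2 CPM, which hold 40.8% and 24.5% of the variance; each point is a library, coloured by group. The 2-mutation libraries separate on the first component and the 5-mutation libraries on the second.

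The unmutated hairpin was compared with the empty vector to ask what the hairpin changed in these neurons beyond the vector itself. More markers of inhibitory neurons, genes of cholesterol synthesis, synaptic genes and voltage-gated ion channel genes fell than rose, and more cell cycle genes, stress response genes, p53 targets and immediate early genes rose than fell. These lists passed camera at its preset correlation, and none passed with a correlation estimated from the data. Erbb4, a neuregulin receptor of interneurons, fell from 153 ± 9.98 to 26.0 ± 7.48 CPM (SD, n = 4), a log2 fold change of −2.55 ± 0.21 (SE; edgeR adjusted p = 5.23e-07). Gad2, which makes GABA, fell from 170 ± 16.5 to 37.9 ± 19.6 CPM. The calcium channel subunit gene Cacna2d2 fell from 43.7 ± 1.32 to 8.78 ± 1.21 CPM. Dgkk, a diacylglycerol kinase gene (ENSMUSG00000062393.13; chromosome X, 6779306 to 6948363), rose from 26.4 ± 4.44 to 152 ± 27.3 CPM, a log2 fold change of 2.51 ± 0.16 (edgeR adjusted p = 2.97e-08).

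After Rtn4, the genes with the greatest falls that met the naming rule were Nxph2 (log2 fold change −2.87 ± 0.15), Hk2, which encodes hexokinase 2 (−2.56 ± 0.41), Erbb4, Lpl, encoding lipoprotein lipase (−2.48 ± 0.11), Cacna2d2 (−2.31 ± 0.09), Gad2 (−2.16 ± 0.37), the neurexin ligand gene Nxph1 (−2.12 ± 0.09), Fam210b (−2.05 ± 0.11) and the Kv3 potassium channel gene Kcnc2 (−2.03 ± 0.11). The greatest rises among genes that met this rule were in Dgkk, Cp (ceruloplasmin, 2.46 ± 0.43), Marveld1 (2.19 ± 0.12), Stac (2.06 ± 0.18), the replication licensing factor gene Cdt1 (1.79 ± 0.12), the ERK phosphatase gene Dusp5 (1.66 ± 0.10), Itga7 (1.66 ± 0.10), Spry4 (1.59 ± 0.11), Etv5 (1.59 ± 0.14) and the neurotrophin gene Bdnf (1.56 ± 0.18). All of these had an edgeR adjusted p of 0.000477 or less.

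Of 20 inhibitory neuron markers, 17 fell, none rose and 3 did not pass (17 adjusted over the list alone; median log2 fold change −1.12; camera adjusted p = 9.16e-13, and adjusted p = 0.303 with an estimated correlation). Among them were Nxph1, Lhx6 (−1.69), a transcription factor gene of the interneuron lineage, and Sst (somatostatin, −1.50). Excitatory neuron markers were split, 5 higher and 5 lower of 18 (5 and 5 adjusted over the list alone; camera adjusted p = 0.244). Of 20 pan-neuronal genes 14 fell and none rose (15 lower adjusted over the list alone; camera adjusted p = 3.48e-09, and adjusted p = 0.103 with an estimated correlation). Among these were Elavl4 (−0.93), Nefh (−1.85) and Rbfox3, which encodes NeuN (−0.50). Postsynaptic genes fell in 20 of 30 and rose in 1 (21 and 1 adjusted over the list alone; camera adjusted p = 1.59e-08, and adjusted p = 0.356 with an estimated correlation). The AMPA receptor genes Gria1 (−1.03) and Gria3 (−0.90) were lower. Presynaptic genes fell in 18 of 30 and rose in 2 (18 and 2 adjusted over the list alone; camera adjusted p = 0.000743, and adjusted p = 0.303 with an estimated correlation). The list included the synaptotagmin gene Syt2 (−3.19). Of 34 voltage-gated ion channel genes 20 fell and 4 rose (20 and 4 adjusted over the list alone; camera adjusted p = 7.71e-09, and adjusted p = 0.303 with an estimated correlation). The list included Cacna1g (−1.11). Of 24 cholesterol synthesis genes 22 fell and none rose (23 lower adjusted over the list alone; median −0.65; camera adjusted p = 5.97e-13, and adjusted p = 0.313 with an estimated correlation). Among these were Nsdhl (−1.21), Lss, which closes the sterol ring (−0.76), and Dhcr7 (−0.52). Axon guidance genes fell in 18 of 32 and rose in 4 (18 and 5 adjusted over the list alone; camera adjusted p = 0.00866, and adjusted p = 0.57 with an estimated correlation). Among these were Slit3 (−1.14) and its receptor gene Robo2 (−1.11). Dendrite and actin genes fell in 10 of 27 and rose in 4 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00866, and adjusted p = 0.57 with an estimated correlation).

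Among the lists that rose, 8 of 20 progenitor and cell cycle genes were higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.472 with an estimated correlation). The members with the smallest p were the replicative helicase genes Mcm6 (log2 fold change 1.48) and Mcm2 (0.91). Of 26 genes of the unfolded protein and integrated stress responses 16 rose and 5 fell (16 and 5 adjusted over the list alone; camera adjusted p = 0.000515, and adjusted p = 0.514 with an estimated correlation). Leading them were the one-carbon enzyme genes Mthfd2 (1.29) and Shmt2 (1.08) and by Chac1 (0.82), a target of the ATF4 pathway. Of 22 p53 targets and apoptosis genes 12 rose and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.000128, and adjusted p = 0.417 with an estimated correlation). Among these were Phlda3 (1.05) and Zmat3 (0.55). Immediate early genes rose in 10 of 25 and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00468, and adjusted p = 0.63 with an estimated correlation). Btg2 (1.17) and Egr1 (0.91) were higher and Egr3 (−0.45) lower. Inflammatory response genes rose in 9 of 14 measured and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0329, not passed with protein-coding genes only, and adjusted p = 0.514 with an estimated correlation), and Icam1 (1.13) rose with them. Of 19 measured genes that miR-124 is known to repress in neurons, 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0217, and adjusted p = 0.514 with an estimated correlation). Among these were Itgb1 (0.63) and Ptpn12 (0.44). Transcripts that host microRNAs rose in 6 of 26 and fell in 11 (6 and 12 adjusted over the list alone; camera adjusted p = 0.00345, not passed with protein-coding genes only, and adjusted p = 0.303 with an estimated correlation). The imprinted noncoding RNAs Rian (−0.76) and Mirg (−0.68) were lower. Astrocyte markers moved both ways, 4 higher and 3 lower of 19 measured (3 and 3 adjusted over the list alone; median 0.25; camera adjusted p = 0.71). The mean levels of oligodendrocyte lineage, microglia and endothelial genes were higher in each unmutated-hairpin library than in each empty-vector library, although these lists did not pass camera (adjusted p = 0.244, 0.335 and 0.287). None of the 15 lists called in this comparison passed with an estimated correlation after adjustment, although 5 had an unadjusted p below 0.05, and the self-contained fry test called 21 lists.

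The 2-mutation hairpin was compared with the empty vector in the same way. More ion channel, postsynaptic and cholesterol synthesis genes fell than rose, and more lysosome and autophagy genes rose than fell. These 4 lists passed camera at its preset correlation and none passed with an estimated correlation, and the lysosome list did not pass without Gm26917 and Gm42418 or with protein-coding genes only. Slc6a7, a proline transporter gene of the brain, fell from 30.1 ± 2.04 to 1.69 ± 0.0484 CPM (SD, n = 4), and Nos1, the neuronal nitric oxide synthase gene, fell from 119 ± 12.0 to 7.06 ± 0.652 CPM. Met, the receptor gene for hepatocyte growth factor, fell from 258 ± 28.4 to 16.5 ± 1.98 CPM. Nefm, a neurofilament gene, rose from 56.9 ± 7.9 to 378 ± 37.8 CPM, a log2 fold change of 2.73 ± 0.17 (edgeR adjusted p = 5.12e-09).

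Among genes that met the naming rule, the greatest falls were in Grp, gastrin releasing peptide (log2 fold change −4.96 ± 0.21; ENSMUSG00000024517.17, chromosome 18, 65872820 to 65886596), Slc6a7 (−4.16 ± 0.08), Nos1 (−4.08 ± 0.08), Met (−3.97 ± 0.14), Hapln1 (−3.86 ± 0.25), Hk2 (−3.74 ± 0.45), Rxfp3 (−3.63 ± 0.16), Mtfp1 (−3.60 ± 0.07), the dynein light chain gene Dynlt3 (−3.46 ± 0.06) and Gad2 (−3.32 ± 0.39). The greatest rises under this rule were in Rgs13 (3.16 ± 0.10), the actin-binding genes Cnn2 (3.10 ± 0.20), Flnc (2.80 ± 0.24) and Tagln2 (2.54 ± 0.19), Nefm, the axonemal genes Dnah1 (2.67 ± 0.11) and Ccdc40 (2.40 ± 0.08), Gtse1 (2.50 ± 0.14), Man2b2 (2.46 ± 0.07) and Ccdc80 (2.43 ± 0.15). Each had an edgeR adjusted p of 6.45e-06 or less.

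Of 34 ion channel genes 29 fell and 4 rose (29 and 4 adjusted over the list alone; median log2 fold change −0.73; camera adjusted p = 6.88e-11, and adjusted p = 0.779 with an estimated correlation). Among these was Scn3b, a sodium channel subunit gene (−2.78 ± 0.04). Postsynaptic genes fell in 23 of 30 and rose in 5 (23 and 5 adjusted over the list alone; camera adjusted p = 1.09e-10, and adjusted p = 0.779 with an estimated correlation). The scaffold gene Dlg2 fell from 809 ± 29.0 to 103 ± 3.98 CPM (log2 fold change −2.98 ± 0.04), and Shank1 (−1.61) and Grm5 (−2.31) fell with it. Cholesterol synthesis genes fell in 21 of 24 and rose in 0 (21 and 0 adjusted over the list alone; median −1.08; camera adjusted p = 6.27e-10, and adjusted p = 0.821 with an estimated correlation). Lss was at −2.38, Fdps at −3.02 and Nsdhl at −1.88. Lysosome and autophagy genes rose in 18 of 26 and fell in 6 (18 and 6 adjusted over the list alone; camera adjusted p = 0.0342, and adjusted p = 0.996 with an estimated correlation). The list included Ulk1, an autophagy kinase gene (1.19), and Npc1 (0.80). Of 20 inhibitory neuron markers 13 fell and 3 rose (13 and 4 adjusted over the list alone; camera adjusted p = 0.058). Pvalb (−4.19 ± 0.31), Calb2 (−3.14 ± 0.17) and Sst (−1.95 ± 0.11) were lower. Excitatory markers went both ways, 7 higher and 8 lower of 18 (7 and 8 adjusted over the list alone; camera adjusted p = 0.921). Among these Mef2c (−1.53) and Camk2a (−1.07) fell and Neurod1 (1.90) and Tbr1 (1.03) rose. Pan-neuronal genes went both ways as well, 8 higher and 10 lower of 20 (8 and 10 adjusted over the list alone; camera adjusted p = 0.921). Presynaptic genes fell in 17 of 30 and rose in 6 (18 and 6 adjusted over the list alone; camera adjusted p = 0.149). The complexin gene Cplx2 was lower (−2.39 ± 0.06) and the vesicle protein gene Sv2a higher (0.84 ± 0.04). Astrocyte markers fell in 8 of 19 and rose in 3 (8 and 3 adjusted over the list alone; camera adjusted p = 0.921). Aldoc and Aqp4 were lower (−1.32 and −2.25) and Clu higher (1.32). Of the 4 lists called, none passed with an estimated correlation after adjustment, 2 had an unadjusted p below 0.05, and fry called 21 lists.

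The 5-mutation hairpin, with the most altered sequence, was compared with the empty vector next. Presynaptic genes and markers of excitatory neurons fell, and these lists passed camera also with an estimated correlation. More inhibitory neuron markers and postsynaptic, ion channel and cholesterol genes fell than rose, and more immediate early and cell cycle genes rose than fell, in lists that passed only at the preset correlation. Slc17a7, the vesicular glutamate transporter VGLUT1 of cortical excitatory neurons (ENSMUSG00000070570.5; chromosome 7, 45163949 to 45176142), fell from 612 ± 27.1 to 81.7 ± 5.81 CPM (SD, n = 4), a log2 fold change of −2.90 ± 0.05 (edgeR adjusted p = 3.78e-20). Rbfox3 fell from 150 ± 2.61 to 31.3 ± 0.873 CPM and Sv2a from 506 ± 16.5 to 128 ± 3.33 CPM. Dusp5 rose from 2.72 ± 0.393 to 22.9 ± 1.73 CPM.

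Among genes that met the naming rule, those with the greatest rises included Itga7 (log2 fold change 3.42 ± 0.10), the fibrillar collagen genes Col3a1 (3.33 ± 0.92) and Col1a1 (2.59 ± 0.70), Serinc2 (3.09 ± 0.14), Dusp5 (3.08 ± 0.10), Crispld2 (2.99 ± 0.08), Hunk (2.75 ± 0.17), Ube2l6 (2.74 ± 0.10) and the relaxin receptor gene Rxfp1 (2.65 ± 0.13). The greatest falls under this rule included those of Hk2 (−3.57 ± 0.44), the adhesion gene Sdk2 (−3.02 ± 0.07), the receptor gene Trhr, Cpne8 (−2.96 ± 0.07), the dynamin gene Dnm3 (−2.93 ± 0.07), Zfp521 (−2.93 ± 0.15), Slc17a7, Reep6 (−2.83 ± 0.12) and Extl1 (−2.69 ± 0.09). Each had an edgeR adjusted p of 0.00768 or less. Without 5-mutation replicate 3, the library with the highest level of both, Col3a1 was at 1.99 and Col1a1 at 1.5, and Col3a1 did not pass with limma voom.

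Of 30 presynaptic genes 23 fell and 3 rose (23 and 3 adjusted over the list alone; camera adjusted p = 2.16e-12, and adjusted p = 0.0109 with an estimated correlation). The list included Sv2a (−1.98), Cplx2 (−2.53) and Vamp2 (−0.67). Of 18 excitatory neuron markers 12 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 1.06e-05, and adjusted p = 0.012 with an estimated correlation). Slc17a7, Mef2c (−1.37), Cux2 (−1.17) and Camk2a (−0.91) were lower. These were the lists that passed with an estimated correlation, and fry called 20. Inhibitory neuron markers fell in 17 of 20 and rose in none (18 and 0 adjusted over the list alone; median −1.25; camera adjusted p = 1.82e-05, and adjusted p = 0.594 with an estimated correlation). Among these were Lhx6 (−1.50) and Pvalb (−1.93). Pan-neuronal genes fell in 10 of 20 and rose in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 5.8e-05, and adjusted p = 0.281 with an estimated correlation). Rbfox3 was at −2.26, Elavl3 at −1.03 and Nefh at −1.93. Postsynaptic genes fell in 21 of 30 and rose in 1 (24 and 2 adjusted over the list alone; camera adjusted p = 1.64e-06, and adjusted p = 0.557 with an estimated correlation). The list included Gria1 (−1.09). Ion channel genes fell in 25 of 34 and rose in 3 (25 and 3 adjusted over the list alone; camera adjusted p = 1.53e-08, and adjusted p = 0.387 with an estimated correlation). The list included Cacna2d2 (−2.49) and Scn8a (−1.19). Cholesterol synthesis genes fell in 22 of 24 and rose in 1 (22 and 2 adjusted over the list alone; median −1.15; camera adjusted p = 2.23e-12, and adjusted p = 0.442 with an estimated correlation). Among these were Sc5d (−1.19) and Lss (−1.19). Unfolded protein and integrated stress response genes fell in 18 of 26 and rose in 4 (18 and 4 adjusted over the list alone; camera adjusted p = 0.00274, and adjusted p = 0.882 with an estimated correlation). Chac1 (−1.43) and Herpud1 (−0.94) were lower. Immediate early genes rose in 17 of 25 and fell in 3 (18 and 3 adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.992 with an estimated correlation). Of these Dusp5 rose, while Jun fell from 103 ± 6.14 to 21.1 ± 7.05 CPM (log2 fold change −2.30). Cell cycle genes rose in 13 of 20 and fell in none (13 and 0 adjusted over the list alone; camera adjusted p = 0.00868, and adjusted p = 0.557 with an estimated correlation). Mcm2 (1.56) and Mcm5 (1.49) were higher. Astrocyte markers fell in 7 of 19 and rose in none (7 and 0 adjusted over the list alone; camera adjusted p = 0.138). Their median was −0.58, and Slc1a2, the glial glutamate transporter gene, was at −0.86.

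**Figure D3:**
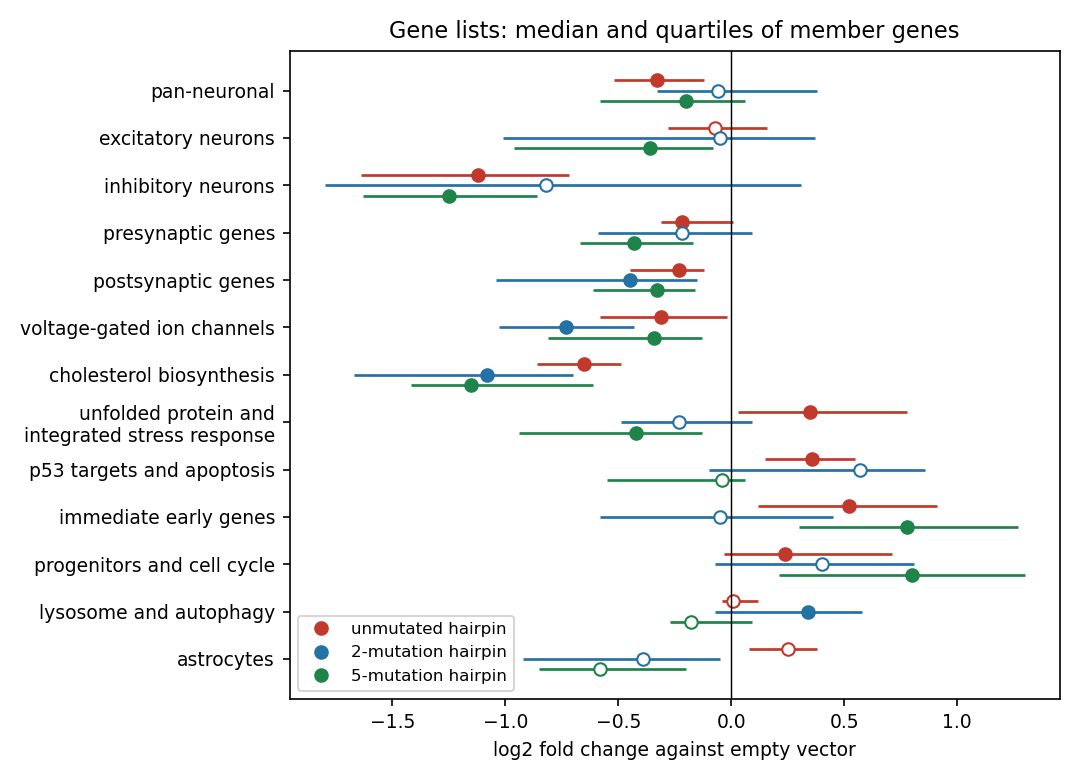
Log2 fold change against empty vector of the genes in each list, as the median (point) and quartiles (line), for the unmutated, 2-mutation and 5-mutation hairpins; filled points are lists with a camera adjusted p below 0.05. Inhibitory neuron markers have medians of −1.12, −0.82 and −1.25 and cholesterol synthesis genes −0.65, −1.08 and −1.15.

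Changes that the 3 hairpins had in common were counted next. The hairpins differ by point mutations only, so a shared change can still depend on the sequence they have in common. In all 3 comparisons 2240 genes passed in the same direction, 1101 higher and 1139 lower. Hk2 fell with each hairpin, from 28.8 ± 8.02 CPM (SD, n = 4) with the empty vector to 4.89 ± 2.3, 2.14 ± 0.134 and 2.32 ± 1.67 CPM with the unmutated, 2-mutation and 5-mutation hairpins. The genes whose smallest fall over the 3 hairpins was largest were Hk2, Gad2 (log2 fold changes −2.16, −3.32 and −2.07), Cacna2d2 (8.78 ± 1.21, 10.9 ± 0.734 and 7.79 ± 1.05 CPM against 43.7 ± 1.32 CPM), Erbb4 (−2.55, −1.75 and −1.68), Nxph1 (−2.12, −1.60 and −1.62). They also included Igfbp5 (−1.46, −1.81 and −2.03), Met (−1.82, −3.97 and −1.37), the sterol carrier gene Stard4 (−1.33, −2.77 and −1.36), Elfn1 (−1.41, −1.24 and −1.38) and Fam210b (−2.05, −1.23 and −1.99). The genes whose smallest rise was largest were Dusp5 (1.66, 1.75 and 3.08), Mcm5 (1.26, 1.58 and 1.49), Cdt1 (1.79, 1.53 and 1.16), Minar2, Slc37a1 (1.11, 1.35 and 1.27). Next came Tcfl5 (1.45, 1.11 and 2.12), the basement membrane collagen genes Col4a2 (1.10, 1.66 and 1.16) and Col4a1, the synaptic immediate early gene Arc (1.39, 1.09 and 1.08) and Serinc2 (1.09, 1.06 and 3.09).

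The mean of the 3 hairpins against the empty vector, tested in the same model, changed 9905 genes, 4960 higher and 4945 lower. Cholesterol synthesis genes fell in 23 of 24 and rose in none (23 and 0 adjusted over the list alone; camera adjusted p = 1.78e-22, and adjusted p = 0.113 with an estimated correlation). Ion channel genes fell in 29 of 34 and rose in 1 (29 and 1 adjusted over the list alone; camera adjusted p = 1.13e-18, and adjusted p = 0.102 with an estimated correlation). Postsynaptic genes fell in 24 of 30 and rose in 3 (24 and 3 adjusted over the list alone; camera adjusted p = 1.21e-16, and adjusted p = 0.113 with an estimated correlation). Inhibitory neuron markers fell in 17 of 20 and rose in none (17 and 0 adjusted over the list alone; camera adjusted p = 8.61e-10, and adjusted p = 0.236 with an estimated correlation). Presynaptic genes fell in 23 of 30 (23 adjusted over the list alone; camera adjusted p = 5.74e-09, and adjusted p = 0.0509 with an estimated correlation). Pan-neuronal genes fell in 12 of 20 (12 adjusted over the list alone; camera adjusted p = 8.24e-05, and adjusted p = 0.144 with an estimated correlation). Excitatory markers fell in 9 of 18 and rose in 5 (9 and 5 adjusted over the list alone; camera adjusted p = 0.00691, and adjusted p = 0.113 with an estimated correlation). Dendrite and actin genes fell in 15 of 27 and rose in 7 (15 and 7 adjusted over the list alone; camera adjusted p = 0.0385, and adjusted p = 0.945 with an estimated correlation). This call was lost without empty-vector replicate 4 and without 2-mutation replicate 2, and that of excitatory markers without unmutated replicate 3. Cell cycle genes rose in 11 of 20 and fell in none (13 and 0 adjusted over the list alone; camera adjusted p = 0.00325, and adjusted p = 0.329 with an estimated correlation).

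The 3 comparisons share the empty-vector libraries, so part of any overlap can come from those libraries. Independent lists of these sizes would share 685 genes over all 3 comparisons, 375 higher and 310 lower. Unchanged groups simulated against the same controls shared at most 0 genes over all 3 and at most 1 in any pair in 20 simulations. These hold no changed genes, so an overlap near 0 follows from the setup and does not show what shared controls add to real lists. With the unmutated and 5-mutation hairpins, 2012 genes were higher in both and 1989 lower in both, against 1153 and 1007 for independent lists, while 1593 moved in opposite directions. With the controls split so that each comparison used different empty-vector libraries, the shared genes were 1427 higher and 1567 lower. With the unmutated and 2-mutation hairpins, 1963 genes were higher in both and 1898 lower in both (1318 and 1170 for independent lists; 1409 and 1516 with split controls), and 2111 were opposite. With the 2-mutation and 5-mutation hairpins, 2594 were higher in both and 2439 lower in both (1801 and 1586 for independent lists; 2058 and 2028 with split controls), and 2849 were opposite. Across genes, which are not independent replicates, fold changes correlated at r = 0.285 (unmutated and 2-mutation), 0.42 (unmutated and 5-mutation) and 0.276 (the mutated hairpins). Simulated values were 0.506, 0.506 and 0.514 and split-control values 0.222, 0.338 and 0.233. The simulated r comes from noise with shared controls and no changed genes, so it cannot be set against the observed r. The covariances were 0.125, 0.157 and 0.17, above the simulated 0.027 by 0.097, 0.129 and 0.142, and 0.105, 0.138 and 0.151 with split controls.

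The hairpins were also compared with one another. Between the unmutated and 2-mutation hairpins 12215 genes differed, 6070 higher and 6145 lower with the unmutated hairpin. Higher with the unmutated hairpin were Grp (log2 difference 4.62 ± 0.21), Dgkk (4.41 ± 0.19), the perineuronal net gene Acan (3.99 ± 0.50), Slc6a7 (3.90 ± 0.08), Dynlt3 (3.84 ± 0.06) and Cyp26b1, which degrades retinoic acid (3.53 ± 0.20). Lower were Nefm (−4.58 ± 0.19), Mbtps2, a protease gene of the sterol regulatory pathway (−2.75 ± 0.05), Phtf2 (−2.61 ± 0.04), Dnah1 (−2.56 ± 0.11) and Nefh (−2.45 ± 0.10), all with an edgeR adjusted p of 1.02e-05 or less. Stress response genes were higher in 18 of 26 and lower in 5 (19 and 5 adjusted over the list alone; camera adjusted p = 0.00455). Among these were the asparagine synthetase gene Asns (2.09). Ion channel genes were higher in 20 of 34 and lower in 8 (20 and 8 adjusted over the list alone; camera adjusted p = 0.00455). Postsynaptic genes were higher in 13 of 30 and lower in 11 (13 and 11 adjusted over the list alone; camera adjusted p = 0.00455). Chromatin regulators were higher in 20 of 29 and lower in 6 (20 and 6 adjusted over the list alone; camera adjusted p = 0.0481). RNAi machinery genes were higher in 15 of 22 and lower in 6 (16 and 6 adjusted over the list alone; camera adjusted p = 0.0481). Pan-neuronal genes were lower in 13 of 20 and higher in 3 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0333), and lysosome genes lower in 17 of 26 and higher in 6 (18 and 6 adjusted over the list alone; camera adjusted p = 0.0481). Each of these 7 calls had an adjusted p = 0.99 with an estimated correlation. With protein-coding genes only, the calls of chromatin, RNAi machinery, pan-neuronal and lysosome genes were lost, and the lysosome call was lost without Gm26917 and Gm42418. Leaving out single libraries ended the calls of chromatin, RNAi machinery and lysosome genes, among them each of 2-mutation replicates 1, 2 and 4.

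Between the unmutated and 5-mutation hairpins 10771 genes differed, 5216 higher and 5555 lower with the unmutated hairpin. Higher were Slc7a3, a cationic amino acid transporter gene (log2 difference 3.07 ± 0.16), Sdk2 (3.01 ± 0.07), Deptor, an mTOR inhibitor gene (2.84 ± 0.14), Slc17a7 (2.81 ± 0.05), Trp53inp2 (2.76 ± 0.05) and the noncoding RNA Tug1. Lower, besides Rtn4 (−4.76 ± 0.05), were Crispld2 (−3.02 ± 0.08), Rxfp1 (−2.88 ± 0.13), Kcnmb2 (−2.70 ± 0.09) and the serotonin receptor gene Htr2a (−2.67 ± 0.24), all with an edgeR adjusted p of 1.41e-07 or less. Stress response genes were higher in 17 of 26 and lower in 3 (17 and 3 adjusted over the list alone; camera adjusted p = 2.34e-07, and adjusted p = 0.605 with an estimated correlation). Chac1 (2.26) and Herpud1 (1.27) were among them. Presynaptic genes were higher in 17 of 30 and lower in 9 (18 and 9 adjusted over the list alone; camera adjusted p = 1.21e-05, and adjusted p = 0.102 with an estimated correlation). Excitatory markers were higher in 12 of 18 and lower in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00101, and adjusted p = 0.096 with an estimated correlation). Targets of p53 were higher in 14 of 22 and lower in 3 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00101, and adjusted p = 0.822 with an estimated correlation). The list included the cyclin gene Ccng1 (2.44). MicroRNA host transcripts were lower in 16 of 26 and higher in 6 (16 and 6 adjusted over the list alone; camera adjusted p = 0.0444, and adjusted p = 0.711 with an estimated correlation). This call was lost with protein-coding genes only and without any of 5 single libraries, unmutated replicates 1 and 2 among them.

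Between the mutated hairpins 12838 genes differed, 6285 higher and 6553 lower with the 2-mutation hairpin. Higher were Rgs13 (log2 difference 4.48 ± 0.12), the cytokine receptor gene Lifr (3.68 ± 0.07), Sdk2 (3.57 ± 0.07), Trp53inp2 (3.44 ± 0.05), the deacetylase gene Sirt2 (3.23 ± 0.05) and Slc17a7 (3.15 ± 0.06). Lower were Acan (−5.43 ± 0.49), Grp (−5.13 ± 0.21), Slc6a7 (−4.70 ± 0.08), Cyp26b1 (−4.36 ± 0.20), the neurofilament gene Prph (−3.73 ± 0.11) and the orexin receptor gene Hcrtr2 (−3.56 ± 0.13). All had an edgeR adjusted p of 3.54e-07 or less. Lysosome genes were higher in 16 of 26 and lower in 7 (16 and 7 adjusted over the list alone; camera adjusted p = 0.00574, and adjusted p = 0.933 with an estimated correlation). Among these were the cathepsin gene Ctsb (2.04). Presynaptic genes were higher in 17 of 30 and lower in 7 (17 and 7 adjusted over the list alone; camera adjusted p = 0.00764, and adjusted p = 0.64 with an estimated correlation). Excitatory markers were higher in 8 of 18 and lower in 5 (8 and 6 adjusted over the list alone; camera adjusted p = 0.0165, and adjusted p = 0.399 with an estimated correlation). Pan-neuronal genes were higher in 11 of 20 and lower in 7 (11 and 7 adjusted over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.933 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 24 of 29 and lower in 1 (24 and 1 adjusted over the list alone; camera adjusted p = 0.00817, and adjusted p = 0.97 with an estimated correlation). Targets of p53 were higher in 15 of 22 and lower in 4 (15 and 5 adjusted over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.97 with an estimated correlation). Immediate early genes were lower in 17 of 25 and higher in 3 (17 and 3 adjusted over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.97 with an estimated correlation). With protein-coding genes only, the calls of excitatory markers, pan-neuronal genes, p53 targets and immediate early genes were lost. The call of immediate early genes was also lost without 5-mutation replicate 3.

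The machinery that makes and uses small RNAs was followed gene by gene, because hairpins and microRNAs share it. Ago2, the Argonaute with slicing activity (ENSMUSG00000036698.11; chromosome 15, 73095844 to 73184935), was measured at 354 ± 21.2 CPM (SD, n = 4) with the empty vector. It rose to 516 ± 30.5 CPM with the unmutated hairpin and fell to 85.4 ± 4.99 CPM with the 2-mutation hairpin, log2 fold changes of 0.55 ± 0.05 and −2.05 ± 0.05 (edgeR adjusted p = 1.25e-08 and 1.19e-18), and was 386 ± 8.2 CPM with the 5-mutation hairpin (log2 fold change 0.13; adjusted p = 0.0373, a call lost with DESeq2's size factors and without several single libraries). Dicer1, which processes hairpins, rose from 105 ± 1.3 to 128 ± 6.44, 200 ± 7.48 and 122 ± 3.5 CPM. Tnrc6b, a GW182 family silencing factor gene, fell with each hairpin (−0.79, −1.16 and −0.41) while its relative Tnrc6a rose (0.42, 1.12 and 0.27). The nuclear exporter gene Xpo5 passed in none of the 3 comparisons (0.07, −0.05 and 0.10), and Drosha fell with the mutated hairpins (−0.40 and −0.17) and was 0.02 with the unmutated hairpin. Of 22 RNAi genes measured, 9 rose and 4 fell, 5 rose and 13 fell, and 9 rose and 8 fell with the unmutated, 2-mutation and 5-mutation hairpins, which adjusted over the list alone became 9 and 4, 5 and 13, and 10 and 8 (camera adjusted p = 0.244, 0.175 and 0.954).

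Effects on microRNA targets were read from the level of transcripts whose 3′ UTR holds a match to a microRNA seed, relative to other transcripts, with UTR length and GC content held constant. Over the 12 hairpin libraries against the 4 empty-vector libraries, transcripts with a site for miR-124, an abundant neuronal microRNA, were higher by 0.063 on the log2 scale, and those with a let-7 site were higher by 0.053 (exact permutation p = 0.0005 for both, the smallest p that 1820 splits can give; adjusted p = 0.0021 over 27 families). The miR-124 score was higher by 0.047 with the unmutated hairpin, 0.065 with the 2-mutation hairpin and 0.077 with the 5-mutation hairpin, and each of the 12 libraries lay above the empty-vector mean, by 0.0398 to 0.0564, 0.0613 to 0.0708 and 0.0625 to 0.094. The let-7 score was higher by 0.019, 0.075 and 0.066. The scores of miR-22 (0.021) and miR-9 (0.011) were also higher over all hairpins, and those of miR-34 (−0.029), miR-21 (−0.025), miR-218 (−0.022), miR-181 (−0.018) and miR-153 (−0.017) were lower, which made 4 families higher and 5 lower. Before adjustment 7 were higher and 7 lower. The permutation of 12 libraries against 4 takes the 3 hairpins as a single group, so its p does not measure whether each hairpin had the shift. The miR-9 scores overlapped those of the empty vector with the unmutated and 2-mutation hairpins (exact permutation p = 0.0571 and 0.1714). Those of miR-153 overlapped with the unmutated hairpin (exact permutation p = 0.1143). With 4 libraries against 4 the smallest exact permutation p is 0.0286, from 70 splits, and an adjusted p below 0.05 needs 16 of the 27 families at that value. By this test 5 families were higher and 13 lower with the unmutated hairpin and 10 higher and 10 lower with the 2-mutation hairpin. For the unmutated hairpin none passed without empty-vector replicate 1, 3 or 4, with 8-base sites only, or without genes with the 7-mers most lowered by a hairpin. None passed with the 5-mutation hairpin, where the lowest adjusted p was 0.0514 and 10 families were higher and 5 lower at an unadjusted exact p below 0.05. This count was 16 without its replicate 2, 18 without its replicate 3, 16 with 8-base sites only, 17 at a mean log2 CPM of at least 4 and 18 without genes with the most lowered 7-mers. Between hairpins, 5 families were higher and 13 lower for the unmutated against the 2-mutation hairpin, 3 and 13 for the unmutated against the 5-mutation hairpin, and 5 and 11 for the 2-mutation against the 5-mutation hairpin. Leaving out any 2-mutation library took the counts of both comparisons with the 2-mutation hairpin to 0, and leaving out any unmutated library did so for the unmutated against the 5-mutation hairpin. The last comparison also gave 0 with 8-base sites only and at a mean log2 CPM of at least 4. Between the mutated hairpins 0 passed without 5-mutation replicate 2 or 4 as well, and without genes with the most lowered 7-mers 0 passed in both comparisons with the 5-mutation hairpin. Without UTR length and GC content in the regression the all-hairpin score of miR-124 was 0.002 and that of let-7 was −0.007, no family passed with the unmutated hairpin or between hairpins, and the families that passed elsewhere were all lower, 24 over all hairpins, 24 with the 2-mutation hairpin and 18 with the 5-mutation hairpin. Among genes with a mean log2 CPM of at least 4 the let-7 score was 0.017 and did not pass.

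**Figure D4:**
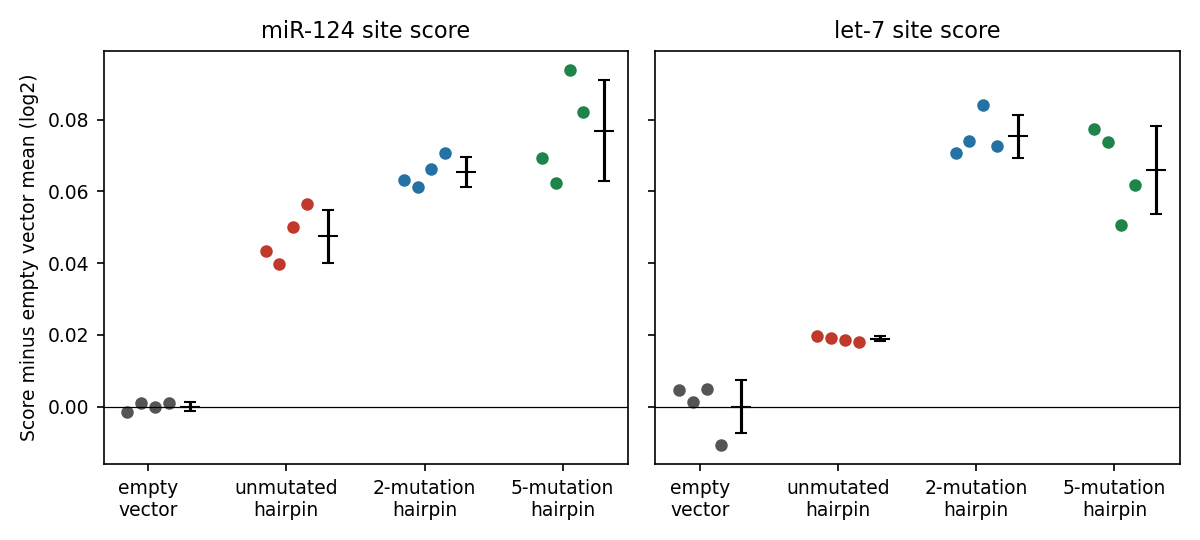
Difference in the miR-124 and let-7 site scores of each library from the empty-vector mean, in log2 units, by group, with the group mean and SD beside the points. The 12 hairpin libraries lie above the empty-vector mean, by 0.0398 to 0.094 for miR-124.

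Neurons express many long genes, and a trend of expression with gene length was tested in each comparison over 19459 genes. Over all of these genes no comparison showed a trend larger than the spread between libraries. The slope of log2 CPM on log2 gene length differed from the empty vector by −0.0054 with the unmutated hairpin (exact permutation p = 0.5143; Spearman's rho of the fold change with length −0.032), by −0.0032 with the 2-mutation hairpin (p = 0.7143, exact; rho 0.019), by −0.0176 with the 5-mutation hairpin (p = 0.2286, exact; rho −0.079) and by −0.0088 over all hairpins (p = 0.3242, exact). Between hairpins the slopes differed by −0.0022, 0.0121 and 0.0143 (exact permutation p = 0.8286, 0.3714 and 0.3143). Without 5-mutation replicate 3 the slope difference of the unmutated from the 5-mutation hairpin was 0.0213 and passed (exact permutation p = 0.0286, the smallest possible). Among the 8254 genes with a mean log2 CPM of at least 4, long genes were lower with the unmutated hairpin (slope difference −0.0267), with the 2-mutation hairpin (−0.0691; exact permutation p = 0.0286 for both, the smallest possible) and over all hairpins (−0.0388; p = 0.0121, exact). With the 5-mutation hairpin (−0.0208; p = 0.1429, exact) and for the unmutated against the 5-mutation hairpin (−0.006; p = 0.6571, exact) the difference did not pass. Between hairpins the differences among these genes turned to 0.0423 for the unmutated against the 2-mutation hairpin and −0.0483 between the mutated hairpins, and both passed (exact permutation p = 0.0286, the smallest possible).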

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

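Each test in this part was planned before its result was seen. In each group of 4 libraries, the gap between the highest or lowest library and its nearest neighbour was divided by the range of the group and compared with Dixon's 95% critical value. Chance passes that value in about 1 of 20 groups, or 38 of the 768 groups tested, and 44 passed. They are given as values, with no explanation tested for any single gene or list. Empty-vector replicate 3 and unmutated-hairpin replicate 3 held 7 of them each and 5-mutation replicate 2 held 6. Leaving these libraries out is among the alternatives in the part on processing.

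Among the mean levels of gene lists, 6 of 168 groups passed: cell cycle genes lowest in 2-mutation replicate 1 (gap over range 0.853), RNAi machinery highest in 5-mutation replicate 2 (0.833), presynaptic genes lowest in unmutated replicate 1 (0.844), axon guidance genes lowest in empty-vector replicate 1 (0.9), cholesterol genes highest in empty-vector replicate 3 (0.9) and p53 targets highest in empty-vector replicate 4 (0.843).

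Among the named genes, 38 of 600 groups passed. In the empty-vector group the highest library stood apart for Cdt1 (0.959), Col1a1 (0.894), Col3a1 (0.903), Fam210b (0.937), all replicate 3, for Htr2a (0.86, replicate 2) and for Mcm2 (0.873, replicate 4), and the lowest for Aldoc (0.898) and Xpo5 (0.841), both replicate 3, Flnc (0.921, replicate 2) and Grm5 (0.836, replicate 1). With the unmutated hairpin it was replicate 3 for Acan (0.917), Bdnf (0.905), Egr3 (0.846), Rian (0.84), Robo2 (0.913) and Stard4 (0.881), each highest, and Mcm6 (0.898), lowest. In the same group Ccdc40 was highest (0.889) and Prph lowest (0.945) in replicate 4, Marveld1 highest (0.856) and Oasl2 lowest (0.924) in replicate 1, and Nefm lowest in replicate 2 (0.841). With the 2-mutation hairpin Kcnmb2 was lowest (0.835) and Rgs13 highest (0.95) in replicate 1, Dusp5 (0.868) and Extl1 (0.917) lowest and Dynlt3 highest (0.834) in replicate 3, and Cplx2 (0.937) and Hk2 (0.836) highest in replicate 4. With the 5-mutation hairpin Robo2 (0.862) and Tug1 (0.89) were highest and Crispld2 (0.848), Grp (0.911) and Mcm6 (0.883) lowest in replicate 2, Btg2 (0.84) and Col4a1 (0.864) highest in replicate 3, Ccdc40 highest in replicate 1 (0.832) and Npc1 highest in replicate 4 (0.832).

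Genes of the unfolded protein and integrated stress responses moved in opposite directions with the unmutated and 5-mutation hairpins, up with the first and down with the second, and the direct comparison of these hairpins gave a camera adjusted p of 2.34e-07 (0.605 with an estimated correlation). Higher with the unmutated hairpin were 17 of 26 genes, and 3 were lower. No explanation of the difference was tested.

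The counts of changed genes were compared with those from other splits of the same libraries. For each comparison of 4 libraries with 4, 1 of the 35 splits gave as many genes, the real one. Every other split mixes libraries of both groups, which widens the spread within each side, so few calls were likely there. The labels do not say whether the libraries of a group came from separate cultures. An effect shared by the libraries of a group would therefore give the same result, and chance is not excluded by these splits. The real counts against empty vector were 7859, 12324 and 10697 for the unmutated, 2-mutation and 5-mutation hairpins, and the highest among other splits 0, 0 and 3. Between hairpins they were 12215 for the unmutated and 2-mutation hairpins (highest other 1), 10771 for the unmutated and 5-mutation hairpins (6) and 12838 for the mutated hairpins (0). For all hairpins against empty vector, 1 of 100 splits gave 9905 genes or more, and the highest other gave 1607, since splits of libraries from 4 distinct groups carry the structure of those groups. For genes changed in the same direction by all 3 hairpins, 1 of 100 splits gave as many as 2240, and the highest other gave 1.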

How the results depend on the processing

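Chosen after the data were seen were the alternatives of protein-coding genes only, of leaving out Gm26917 and Gm42418, of leaving out genes with the most lowered 7-mers, and of leaving out single libraries for the length slope. The counts of changed genes stayed within 1.5 times under DESeq2's size factors, upper quartile scaling, either filter, DESeq2's Wald test, limma voom, fits of only the groups compared (not possible for all hairpins together), a block for the replicate number and both alternatives chosen later. By DESeq2's Wald test they were 7734, 12139 and 10493 for the unmutated, 2-mutation and 5-mutation hairpins against empty vector. Under these alternatives between 86.7% and 100% of the genes called and still tested were called, none in the opposite direction. With a fold threshold of 1.2, 3143 genes passed with the unmutated hairpin, 6337 with the 5-mutation hairpin, 6298 between these hairpins, 4286 over all hairpins and 777 in all 3, because smaller changes are left out by construction. The other contrasts stayed within 1.5 times.

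Leaving out 1 library gave 7021 to 8363, 11679 to 12660 and 10083 to 10832 genes for the unmutated, 2-mutation and 5-mutation hairpins against empty vector. It gave 11665 to 12519 for the unmutated against the 2-mutation hairpin, 10078 to 10784 for the unmutated against the 5-mutation hairpin and 12251 to 13038 between the mutated hairpins. Over all hairpins it gave 8919 to 10544, and 1952 to 2442 genes in all 3. For single named genes, 23955 results under an alternative kept direction and side of the threshold, 350 kept direction but no longer passed (115 of these under the fold threshold and 175 with a library left out), and none reversed.

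With an estimated correlation the numbers of lists called were 0 of 15 (unmutated), 0 of 4 (2-mutation) and 2 of 10 (5-mutation), and 0 in each of the other 4 contrasts by camera. At an unadjusted p below 0.05 that version passed 5, 2 and 4 lists, and 1, 2, 2 and 6 in the others. The fry test called 21 (2-mutation), 20 (5-mutation), 18 (unmutated against 2-mutation), 18 (unmutated against 5-mutation), 23 (between the mutated hairpins) and 19 (all hairpins). With protein-coding genes only, 3 lists were called between the unmutated and 2-mutation hairpins and 3 between the mutated hairpins, and the cause was not tested. Leaving out 1 library gave 15 to 16, 4 to 5 and 10 to 12 lists against empty vector, 4 to 9, 4 to 6 and 6 to 8 between hairpins, and 8 to 12 over all. The 4 lists between the unmutated and 2-mutation hairpins came without empty-vector replicate 2, unmutated replicate 3, 2-mutation replicates 1, 2 or 4, or 5-mutation replicate 4.

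The number of microRNA families called turns on a step, since with 4 libraries against 4 an adjusted p below 0.05 needs 16 of the 27 families at the smallest exact p. With 8-base sites only, 0 were called for the unmutated hairpin (14 at an unadjusted p below 0.05), 16 for the 5-mutation hairpin and 0 (13) between these. At a mean log2 CPM of at least 4 there were 17 for the 5-mutation hairpin and 0 (14) for the unmutated against the 5-mutation hairpin. Without UTR length and GC content there were 0 (9) for the unmutated hairpin, 18 for the 5-mutation hairpin, 0 (13), 0 (4) and 0 (7) between hairpins, and 24 over all hairpins. All calls without them were lower, those of the 2-mutation hairpin (24) included, and the let-7 score over all hairpins reversed to −0.007. Without genes with the most lowered 7-mers there were 0 (12) for the unmutated hairpin, 18 for the 5-mutation hairpin, 0 (12) for the unmutated against the 5-mutation hairpin and 0 (14) between the mutated hairpins. Leaving out 1 library gave 0 to 18, 18 to 21 and 0 to 18 families against empty vector, 0 to 19, 0 to 17 and 0 to 16 between hairpins, and 7 to 10 over all. None were called for the unmutated hairpin without empty-vector replicate 1, 3 or 4. Between hairpins none were called without any 2-mutation library for the unmutated against the 2-mutation hairpin, without any unmutated library for the unmutated against the 5-mutation hairpin, and without any 2-mutation library or 5-mutation replicate 2 or 4 between the mutated hairpins. For the 5-mutation hairpin 16 passed without its replicate 2 and 18 without its replicate 3.

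At a mean log2 CPM of at least 4 the length slopes were −0.0267 (unmutated), −0.0691 (2-mutation) and −0.0388 (all hairpins), all past the threshold, and −0.0208 (5-mutation) and −0.006 (unmutated against 5-mutation), which did not pass. They reversed between hairpins, to 0.0423 for the unmutated against the 2-mutation hairpin and −0.0483 between the mutated hairpins, both past the threshold, and the cause was not tested. Leaving out 1 library gave −0.0107 to −0.0002, −0.0085 to 0.002 and −0.0268 to −0.0092 against empty vector, −0.0072 to 0.003, 0.0038 to 0.0213 and 0.006 to 0.0235 between hairpins, and −0.014 to −0.0035 over all. The slope of the unmutated against the 5-mutation hairpin passed, at 0.0213, without 5-mutation replicate 3.

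The replicate number was also used as a block. Of the 24 pairs of libraries with the same number in different groups, 12 had residuals correlated above 0.1 (−0.021 to 0.272; median 0.099 against −0.032 for other pairs), and 15 of 16 libraries correlated best with their own number. With the block 8589, 12724 and 11171 genes changed against empty vector, 10546 over all hairpins and 2504 in all 3. For the microRNA families a block of 4 numbers allows an exact p no smaller than 0.125, so 0 could be called in any comparison of 4 with 4, and 7 were called over all hairpins.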

Other observations

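The gene lists here did not pass camera with any hairpin against empty vector. Interferon-stimulated genes rose in 13 of 21 and fell in 2 with the 2-mutation hairpin (13 and 2 adjusted over the list alone; camera adjusted p = 0.175), with the antiviral genes Oasl2 at 4.84 ± 0.49 and Mx1 at 3.68 ± 0.41 on the log2 scale (SE). They rose in 7 and fell in 2 with the unmutated hairpin (camera adjusted p = 0.327) and went 4 and 4 with the 5-mutation hairpin (camera adjusted p = 0.995). Of 10 interferon sensors 4, 3 and 1 rose and 1, 0 and 3 fell with the unmutated, 2-mutation and 5-mutation hairpins (camera adjusted p = 0.244, 0.804 and 0.995), with the double-stranded RNA sensor Ifih1 higher by 0.91 and 1.44 in the first pair of these. Of 34 cytosolic ribosomal protein genes 2, 21 and 4 rose and 0, 2 and 2 fell (0, 21 and 2 higher adjusted over the list alone; camera adjusted p = 0.327, 0.201 and 0.995), and of 29 oxidative phosphorylation genes 4, 16 and 3 rose and 5, 2 and 16 fell (camera adjusted p = 0.643, 0.132 and 0.132). Heat shock genes rose in 5, 8 and 5 of 16 and fell in 4, 5 and 4 (camera adjusted p = 0.608, 0.269 and 0.995). Injury response genes rose in 7, 5 and 4 of 19 and fell in 4, 8 and 6 (camera adjusted p = 0.915, 0.991 and 0.633), and replication-dependent histones rose in 5, 6 and 9 of 17 and fell in 1, 4 and 5 (camera adjusted p = 0.199, 0.538 and 0.481). Activity-regulated late genes and neuropeptides rose in 11, 7 and 11 of 20 and fell in 4, 8 and 5 (camera adjusted p = 0.287, 0.964 and 0.476).

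Lists of markers of cell types other than neurons and astrocytes did not pass camera. Oligodendrocyte lineage genes rose in 6, 1 and 4 of 11 measured and fell in 1, 3 and 3 with the unmutated, 2-mutation and 5-mutation hairpins (camera adjusted p = 0.244, 0.921 and 0.601). Microglia genes rose in 2, 2 and 1 of 6 and fell in 1, 2 and 4 (camera adjusted p = 0.335, 0.964 and 0.891), endothelial and mural genes rose in 4, 2 and 6 of 16 and fell in 2, 3 and 4 (camera adjusted p = 0.287, 0.964 and 0.995), and fibroblast genes rose in 2, 1 and 7 of 18 and fell in 1, 7 and 5 (camera adjusted p = 0.738, 0.804 and 0.995). With the unmutated hairpin the mean log2 levels relative to the empty vector were 0.181 to 0.41 for oligodendrocyte lineage genes, 0.211 to 0.342 for microglia genes and 0.255 to 0.506 for endothelial genes, above the highest empty-vector library of each (0.061, 0.172 and 0.232). With the 5-mutation hairpin replicate 3 was highest, at 1.616 for fibroblast genes (−0.258 to 0.266 in the others) and 1.138 for endothelial genes (−0.43 to 0.34). The antigen processing gene Cd68, also expressed outside microglia, was 4.0 ± 0.18 CPM with the empty vector, 9.55 ± 0.54 CPM with the unmutated, 4.3 ± 0.172 CPM with the 2-mutation and 11.6 ± 2.28 CPM with the 5-mutation hairpin (SD, n = 4).

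In the weighing of patterns here, the tests of astrocyte markers and of markers of inhibitory neurons called higher were chosen after the results were seen, and the 7-mers were found in the scan of the same data. The first pattern is a sequence in 3′ UTRs whose genes fell most with one hairpin and far less with the others. Genes with ATGAAAC in the UTR were lower by −0.215 with the unmutated hairpin (1599 genes), those with ATGACAA by −0.442 with the 2-mutation hairpin (1486 genes) and those with CTAACCA by −0.370 with the 5-mutation hairpin (1102 genes), each the most lowered of 15900 7-mers in its own comparison. With the other hairpins the coefficients lay between −0.031 and −0.010, and in the 4 libraries of the hairpin against those of the empty vector the score differences were −0.216, −0.437 and −0.370 (exact permutation p = 0.0286 for each, the smallest possible). With the other hairpins they were −0.035 (2-mutation) and −0.015 (5-mutation) for ATGAAAC, −0.028 (unmutated) and −0.019 (5-mutation) for ATGACAA, and −0.012 (unmutated) and −0.015 (2-mutation) for CTAACCA. The exact permutation p of these was 0.0857 for ATGAAAC with the 5-mutation hairpin and again 0.0286 for the others. UTR composition is argued against by the reverse complements, whose coefficients were at most 0.05 of those of the 7-mers. The 7-mers found in replicates 1 and 2 ranked 1 in replicates 3 and 4 with each hairpin, which argues against noise of single libraries. Both sets measure the same genes, however. A 7-mer found by chance in genes changed for another reason would rank high in both, so that is not excluded. A candidate explanation that the values allow is pairing of each hairpin's own seed: genes with 2 or more sites were lower than genes with 1 site by −0.264 ± 0.035, −0.381 ± 0.063 and −0.339 ± 0.076 (SE), although the hairpin sequences are not in the labels, so the seeds cannot be compared with them.

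The most lowered 8-mers were ATGAAACA (−0.269, 640 genes), ATGACAAA (−0.504, 570 genes) and TCTAACCA (−0.397, 358 genes). From ATGAAACA the others differ at 2 and 4 positions in turn, within the 2 and 5 mutations of their hairpins. Of 6 annotated coding transcripts of Rtn4, 3 hold ATGAAACA. It lies at chromosome 11, 29707499 to 29707506, in the coding sequence and at 29743020 to 29743027 in the 3′ UTR. Rtn4 may be the transcript the unmutated hairpin was designed against, since its level was graded with the number of mutations. It was 29.9 to 31.3 (unmutated), 122 to 130 (2-mutation), 773 to 856 (5-mutation) and 837 to 891 CPM (empty vector). The 8-mer, found in these same data, is weak evidence by itself. It is held by 8.7% of genes (1253 of 14460) in the longest coding transcript, Rtn4 among them. Which site, if either, the hairpin pairs with was not tested.

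The second pattern is the higher level of genes with miR-124 and let-7 sites over the 3 hairpins. Composition of the sites is argued against by their reverse complements, whose largest coefficient relative to the site was −0.29, although without UTR length and GC content in the regression the scores were 0.002 and −0.007, so the pattern rests on that correction. More non-neuronal cells stay open for each hairpin. Astrocyte markers had medians of 0.25, −0.39 and −0.58 with the unmutated, 2-mutation and 5-mutation hairpins, but the mean levels of the list in single libraries overlapped with those of the empty vector, and other non-neuronal types were not excluded. Of the families called over all hairpins, 4 had higher and 5 had lower site scores, so the scores do not show a general loss of microRNA activity. Competition of hairpins with microRNAs for the shared machinery is a hypothesis the design allows for the miR-124 and let-7 scores. It was not tested apart from other causes, since small RNAs were not measured.

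The third pattern is the fall of inhibitory neuron markers and cholesterol genes with each hairpin. The empty-vector libraries were also taken in pairs, against which the lowest ratio of a list's median to that against all 4 was 0.89. The falls therefore did not rest on single control libraries. A deviation common to all 4 would be in each pair, so this test cannot exclude chance values of the shared controls. Fewer inhibitory neurons may account for the markers with the unmutated and 5-mutation hairpins, where the highest called marker was −0.56 and −0.69 and none was called higher. With the 2-mutation hairpin the called markers went up to 1.04 (3 were higher, with Dlx2 and Dlx5, looked up after the values were seen, among them), which a loss of these cells alone does not give. Whether cells were lost or lowered these transcripts stays open for the first pair, and no explanation of the cholesterol genes was tested beyond the shared controls.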
